A study of Mus musculus with 63 samples.

How the data were processed

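Single granulocyte-monocyte progenitors from the bone marrow of C57BL/6 mice labelled Irf8-/- were separated on the Fluidigm C1 system, cDNA was made with the SMARTer kit and libraries with the Nextera XT kit, per the labels' protocols. Bowtie2 (an aligner), RSEM (which estimates transcript abundance) and the mouse build mm9 are named in the submitters' processing notes, without versions or settings. Other steps are not given in the sources used here. The deposited values are log2 of TPM plus 1, found from the values: transformed back, each column of 23955 genes sums to 1e+06. The design had assumed TPM, so the log2 values deposited by the authors were transformed back exactly and the planned tests were kept. TPM is relative to a fixed total, so a gene that takes a larger share lowers the others, and it keeps no read totals, so the depth per cell is unknown and no count model was used. RSEM can divide reads among genes with shared sequence, which affects gene families and paralogs. C1 chips can capture more than 1 cell. No doublet caller was run, and the highest number of genes at 1 TPM in a cell was 5039. The protocol as described uses no molecular identifiers, so amplification adds to the spread between cells.

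All 63 columns were matched to the samples by cell number, and per-sample columns not used numbered 0. The 62 cells of the group were analysed, and the cell marked as poor quality (number 23) was left out. No pair of cells were duplicates, since the highest Spearman correlation between cells was 0.669 (median 0.573). Because no label ties cells to animals, the group is 1 sample. Permutation p-values and the SDs over cells measure only association and spread among these cells.

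A gene counted as detected at 1 TPM or more. A total of 18 gene lists were fixed before the data were examined: primary granule, late neutrophil, monocyte-dendritic, stem and early progenitor, megakaryocyte-erythroid, basophil and mast cell, eosinophil, lymphoid, stromal and endothelial, macrophage, G1/S, G2/M, transcription factor, sort marker, cytokine receptor, interferon response, stress and immediate early, and apoptosis regulator. For each list the share of cells with at least 3 detected members was given with an exact (Clopper-Pearson) 95% interval. These shares were not set beside random lists, so a high share alone does not show that a list stood out. Coordination was the mean pairwise Spearman correlation of members detected in at least 10% of cells, as a percentile among 10000 random lists matched on size and mean expression. Percentiles above 97.5, or as far down at the other end, were read as standing apart. Scores were the mean log2(TPM + 1), with a pseudocount of 1, of such members minus the mean of 20 control genes per member drawn from 25 expression bins. Genes on both lists of a pair were dropped. Correlations were tested with 100000 permutations, two-sided, with Benjamini-Hochberg adjustment over 10 pairs. Genes detected in at least 20% of cells, score members left out, were correlated with 3 scores, and counts beyond 0.5 and -0.5 were set beside 100 permutations of the score. Clusters came from 500 variable genes detected in 10 to 90% of cells, with the cell type and cell cycle lists left out, 10 principal components and Ward clustering, with the number from 2 to 6 that had the highest silhouette.

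Genes were named from sets fixed by rule, and not every member of a set is printed. The sets were the members with the highest and lowest detection per list, and the transcription factors and sort markers. Further sets were the 15 highest and 10 lowest genes per score (predicted, ribosomal protein and mitochondrial genes left out). The leading genes by mean level, by residual variance and per cluster completed them. Irf8 and Gfi1 against the scores were added after the Irf8 levels were seen and before their correlations were. The single-gene pairs with Irf8 and the omission of Ly6a and Cxcr2 from the scores were added after the correlations were seen. The alternatives tried were pseudocounts of 0.1 and 10, other detection limits, no filter on low values, inclusion of the poor quality cell, omission of cells with few detected genes, a size factor per cell, partialling out the number of detected genes, other score definitions, and other cluster settings. The closing section gives their effect.

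The procedure was tested on simulated data of 62 cells. Each gene's values were shuffled over cells, and planted genes and the late neutrophil members were then reordered to follow a hidden order of the cells. The monocyte-dendritic members were reordered to follow it in reverse. Among 6569 genes, 93% of those planted at a correlation of 0.8 with that order reached 0.5 with the late neutrophil score. So did 2% of those planted at 0.4 and 0 of 6173 unplanted genes, so weak relations are mostly missed by the limit. The planted opposite pair, late neutrophil with monocyte-dendritic, was recovered at rho -0.690 (permutation test, adjusted p = 0.0005). None of 9 unplanted score pairs was called. The shuffling removed any link that genes share through the number of detected genes. The absence of unplanted calls therefore does not cover false calls from that source. Of the lists tested for coordination, the planted one lay at percentile 100 and the unplanted one at percentile 2.4, beyond the lower limit, so a low percentile can arise without any planted relation. Shared sequence was tested with 31-base stretches of GENCODE transcripts matched by gene symbol. That annotation belongs to another mouse build than the one in the processing notes, so no coordinates are given. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, statsmodels 0.14.6 and matplotlib 3.10.9.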

Results

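The transcriptomes of single granulocyte-monocyte progenitors (GMP), the bone marrow progenitors that give rise to neutrophils and monocytes, were measured in C57BL/6 mice labelled Irf8-/-. Irf8 encodes a transcription factor needed for monocyte and dendritic cell development. The series held 63 cells, sorted as lineage-negative, Kit-positive, Sca-1-negative, CD16/32-positive and CD34-positive, of which 62 were analysed and 1 was marked by the submitters as being of poor quality. A mean of 3987 ± 569 genes (SD over 62 cells) reached 1 TPM (transcripts per 1e+06 transcripts) in a cell, with a range of 2337 to 5039. The read depth behind each cell is unknown, since TPM values keep no read totals. All cells carried the same genotype label and no label tied a cell to an animal, so the 62 cells count as 1 sample, no comparison with wild-type cells was made, and SDs and p-values below describe the spread and association among these cells only. A value under 1 TPM in a single cell was read as not detected, not as absence of the transcript. Exact binomial intervals cover the counting of cells only.

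The targeted gene was examined first. Irf8 transcript was detected at 1 TPM or more in 51 of the 62 cells, or 82.3% (exact 95% interval 70.5 to 90.8%). Its level averaged 494 ± 517 TPM (SD, 62 cells), with a median of 399 TPM and a maximum of 2443 TPM. Irf8 reached 100 TPM in 42 cells and was listed at 0 in 5 cells. By mean level it ranked 320th among the genes. The values are summed over the whole gene, and the labels do not say which part of Irf8 was deleted, so the transcript level checks neither the deletion nor the protein. The cells are therefore referred to as cells labelled Irf8-/-.

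The question of which lineage programmes these progenitors carried was addressed with gene lists fixed before the data were examined. The primary granule list, the proteases and other proteins made in early neutrophil and monocyte precursors, held the 2 genes with the highest mean level. All 18 of its members were detected, 16 of them in at least 90% of cells. Mpo, the granule peroxidase, had the highest mean of all genes at 32538 ± 12950 TPM, followed by Elane, which encodes neutrophil elastase, at 29180 ± 10694 TPM. Prtn3 averaged 5141 ± 1831 TPM and Ctsg 3608 ± 1541 TPM, and both were detected in every cell. The exceptions to the near-uniform detection were Fcnb, in 47 cells (75.8%, exact interval 63.3 to 85.8%), and Cd63, in 36 cells (58.1%, 44.8 to 70.5%).

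Members of the late neutrophil list, which covers secondary granule and later genes, were detected unevenly. Of the 27 members in the file, 6 did not reach 1 TPM in any cell, among them Ltf and Mmp9, which encode lactoferrin and gelatinase. Anxa1 was detected in all 62 cells and S100a8, a calcium-binding protein of neutrophils and monocytes, in 61. S100a8 had rank 3 by mean level and its SD exceeded its mean (18140 ± 33201 TPM, median 4541 TPM). The related S100a9 was detected in 49 cells, Lcn2 in 48, Camp in 13 and Ngp in 12. Cebpe, a transcription factor of late granulocyte maturation, was detected in 21 cells (33.9%, exact interval 22.3 to 47.0%). Cxcr2 was listed at 1 TPM or more in 61 cells at a mean of 24.5 ± 22.5 TPM, but its transcript shares sequence with abundant genes, so that value is uncertain.

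The monocyte-dendritic list was represented by part of its members in every cell. A median of 8 of its 32 members was detected per cell, with a range of 3 to 14, and 11 members did not reach 1 TPM in any cell. F13a1, Ly6c2 and Emb were detected in all 62 cells, with means of 1226 ± 816, 6397 ± 3379 and 694 ± 443 TPM. Ms4a6c was detected in 53 cells, the chemokine receptor gene Ccr2 in 51 and Zeb2 in 44. Csf1r, the receptor for macrophage colony-stimulating factor, was detected in 23 cells (37.1%, exact interval 25.2 to 50.3%) and Klf4 in 7. Irf5 was detected in 2 cells. The members below 1 TPM in every cell included Mafb, Ly86, Cd74 and Batf3.

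**Figure D1:**
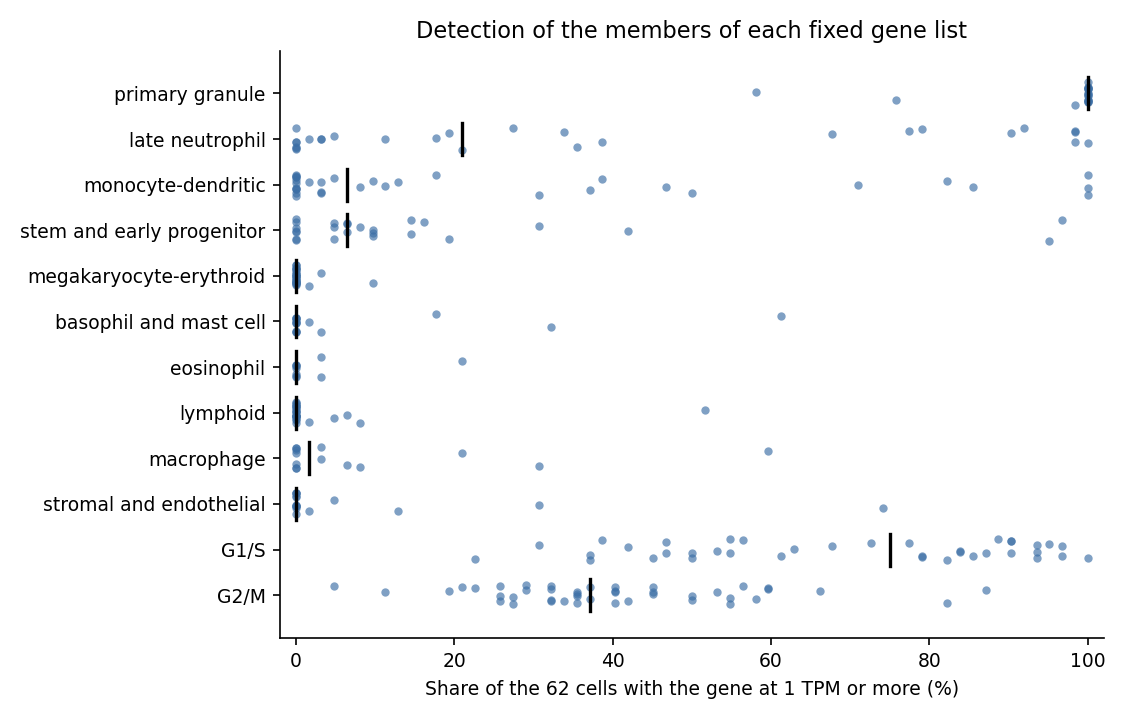
Share of the 62 cells, in percent, in which each gene reached 1 TPM, for 12 of the fixed gene lists. Each point is 1 gene, moved at random along the vertical axis for visibility, and each black bar is the list's median. Most primary granule members lie close to 100%, while most megakaryocyte-erythroid and lymphoid members lie at 0%.

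Markers of other cell types were seldom detected together at 1 TPM. The sort would have removed mature cells of these types, so low shares say little beyond the sort itself. At least 3 members of the megakaryocyte-erythroid list, of the eosinophil list or of the lymphoid list were detected in 0 of 62 cells, for which the exact interval reaches 5.78%. Gata1, Klf1 and the listed globin genes were below 1 TPM in every cell. At least 3 basophil and mast cell members were found in 2 cells, stromal and endothelial members in 2 cells and macrophage members in 4 cells (6.45%, exact interval 1.79 to 15.7%). With any value above 0 as detected, the basophil and mast cell share was 12.9% and the macrophage share 17.7%, and at 10 TPM the stromal share was 0%. Single members of these lists were nevertheless frequent. Hdc, the histidine decarboxylase gene, was detected in 38 cells, the macrophage glycoprotein gene Cd68 in 37, the B-cell receptor component Cd79b in 32 (51.6%, exact interval 38.6 to 64.5%) and Lepr in 46 at a mean of 3.41 ± 4.00 TPM. Lepr shares sequence with abundant genes, so its value is uncertain.

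At least 3 of the 25 members of the stem and early progenitor list were detected in 49 cells (79.0%, exact interval 66.8 to 88.3%), with a median of 3.5 members per cell. Ly6a and Lmo2, the latter in 59 cells, were the members detected in at least 90% of cells. The share was neither computed without Ly6a nor set beside random lists, so it does not show that this list stood out. Ly6a, which encodes Sca-1, was detected in 60 cells at 65.8 ± 40.6 TPM, although the sort excluded Sca-1-positive cells, and its transcripts share sequence with the abundant Ly6c2. Mecom, Procr and Slamf1 did not reach 1 TPM in any cell. Of the markers used for sorting, Kit was detected in 55 cells (88.7%, exact interval 78.1 to 95.3%), the CD16 gene Fcgr3 in all 62 and Cd34 in 12 (19.4%). Cd3e, Cd4 and Cd19 were below 1 TPM in every cell, while Itgam was detected in 22 cells, Cd8a in 5 and Flt3 in 4.

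Of the 40 listed transcription factors, 9 did not reach 1 TPM in any cell, among them Irf4, Gata1, Gata2 and Gfi1b. Myb was detected in 61 cells and Myc in 50. Gfi1, a repressor needed for neutrophil development, was detected in 34 cells (54.8%, exact interval 41.7 to 67.5%) at 49.1 ± 91.4 TPM. The myeloid factors Cebpa and Spi1 were detected in 44 and 35 cells, and Ets1 in 29. Cell cycle transcripts were present throughout, since 3 or more G1/S members were detected in all 62 cells and 3 or more G2/M members in 60.

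Members of several lists varied together across the cells. Among members detected in at least 10% of cells, the mean pairwise Spearman correlation was 0.310 for 42 G2/M members, 0.173 for 38 G1/S members, 0.166 for 17 late neutrophil members and 0.153 for 18 primary granule members. Each of these lay at percentile 99.97 or higher among 10000 random lists matched on size and mean expression, whose medians were 0.0258, 0.0299, 0.0208 and 0.0378. The highest late neutrophil pair was S100a8 with S100a9 (rho 0.764), and the highest primary granule pair was Elane with Srgn (rho 0.652). The 14 monocyte-dendritic members correlated at a mean of 0.0695, at percentile 99.1, led by F13a1 with Ccr2 (rho 0.543), whereas Ly6c2 had a mean correlation of -0.158 with the other members. The 8 stem and early progenitor members did not stand apart from random lists (mean 0.00337, percentile 30.9), although without the filter on low values their percentile was 99.4. Low percentiles are read with caution, since a simulated list without planted relations reached percentile 2.4. The 27 transcription factors lay below almost all random lists (mean -0.00617, percentile 0.01), and with the number of detected genes partialled out they no longer lay below the lower limit (percentile 5.60). The sort markers (9 members, percentile 13.8), basophil and mast cell members (3, percentile 45.5) and stromal and endothelial members (3, percentile 30.3) did not stand apart. The 3 macrophage members Emr1, Slc40a1 and Cd68 had a mean of -0.143 (percentile 0.94), but lay at percentiles 2.75 to 18.9 under 3 alternative settings.

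Cells with a high primary granule score tended to have a high late neutrophil score and a low monocyte-dendritic score. Per-cell scores, the mean log2(TPM + 1) of a list's members minus that of expression-matched control genes, were compared in 10 pairs of 5 scores with two-sided permutation tests and Benjamini-Hochberg adjustment. The primary granule and late neutrophil scores correlated at Spearman rho 0.694 (p = 1e-05, the smallest the permutations can give, adjusted p = 0.0001) and Pearson r 0.565 (p = 1e-05), and r was 0.597 without the 2 cells farthest from the median. The primary granule and monocyte-dendritic scores correlated negatively (rho -0.407, p = 0.00109, adjusted p = 0.00545, Pearson r -0.407, p = 0.00099, r without 2 cells -0.383). The late neutrophil and monocyte-dendritic scores did so more weakly (rho -0.319, p = 0.0115, adjusted p = 0.0288, Pearson r -0.321, p = 0.0105, r without 2 cells -0.291), as did the monocyte-dendritic and cell cycle scores (rho -0.358, p = 0.00409, adjusted p = 0.0136, Pearson r -0.352, p = 0.00505, r without 2 cells -0.348). The other 6 pairs did not pass the adjusted threshold of 0.05, and their rho values ran from -0.191 to 0.0857. Of these, the late neutrophil and stem and early progenitor pair (rho -0.170) passed once Ly6a was left out (rho -0.321, adjusted p = 0.0239).

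**Figure D2:**
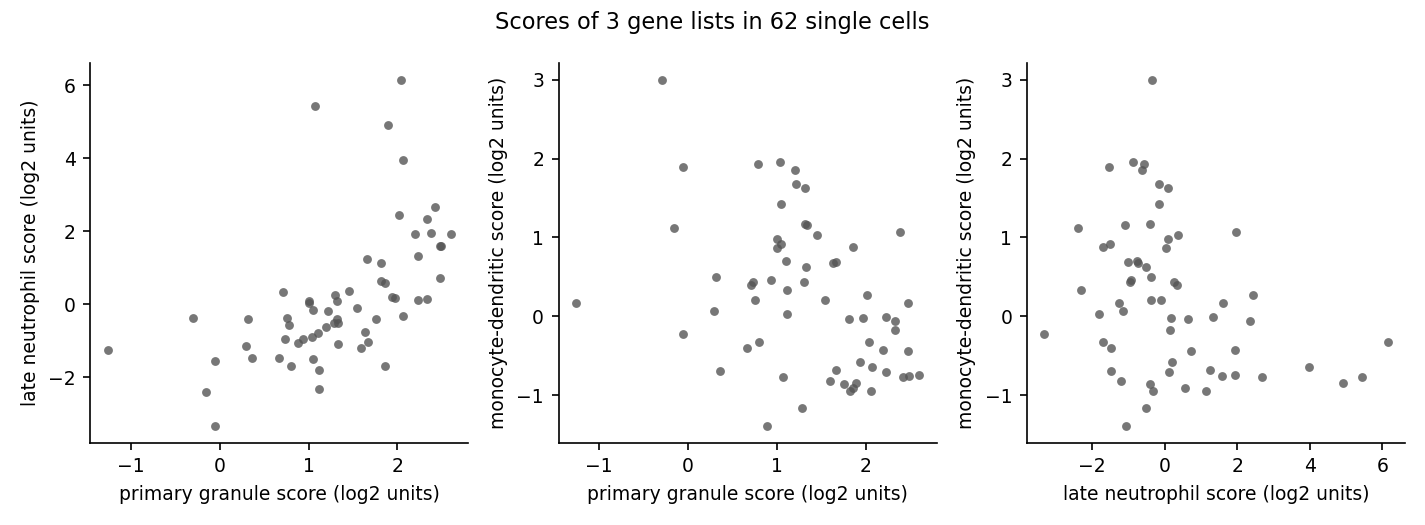
Scores of the primary granule, late neutrophil and monocyte-dendritic lists in 62 single cells, in log2 units relative to control genes, with 1 point per cell. The primary granule and late neutrophil scores rise together (rho 0.694), while each is negatively related to the monocyte-dendritic score (rho -0.407 and -0.319).

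Not all of these relations held under other settings. The negative relation of the late neutrophil and monocyte-dendritic scores missed the threshold under 5 alternatives, including the omission of Ccr2 alone (rho -0.232, adjusted p = 0.173). That of the monocyte-dendritic and cell cycle scores was not seen with a plain mean of members (rho 0.00562) or with z-scored members (rho -0.00531), and with z-scored members the primary granule and monocyte-dendritic pair missed the threshold too (rho -0.184, adjusted p = 0.304). Within the 2 cell clusters described below, of 33 and 29 cells, the primary granule and late neutrophil scores correlated at rho 0.655 and 0.654. The primary granule and monocyte-dendritic scores did so at -0.332 and -0.635, and the late neutrophil and monocyte-dendritic scores at -0.246 and -0.706. The monocyte-dendritic and cell cycle scores did so at -0.323 and -0.232. Among the pairs that did not pass, the late neutrophil and cell cycle scores had a pooled rho of -0.0844, but 0.177 and 0.303 within the clusters. The primary granule and cell cycle scores likewise had -0.0704 pooled, but 0.0856 and 0.153 within.

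Genes outside each list were then ranked by their Spearman correlation with its score, without a test per gene. Of 6569 genes, 16 correlated with the late neutrophil score at 0.5 or more and 25 at -0.5 or less, against means of 0.17 and 0.16 genes and highest counts of 3 and 2 over 100 permutations of the score. With a size factor per cell the counts were 29 and 13, which turns the balance towards the positive side. The positive side held the primary granule genes Fcnb (rho 0.725), Srgn (0.537) and Gstm1 (0.519), the cytoskeletal regulator genes Tmsb4x (0.700), Arhgdib (0.698) and Cnn2 (0.555), and Ly6c2 (0.624), S100a11 (0.573) and the transcription factor gene Ets1 (0.618). Ly6a had the highest value (0.726) and carries the uncertainty given above. The negative side held the chaperone gene Hsp90ab1 (-0.675), Set (-0.667), the histone variant gene H2afy (-0.643), Sod1 (-0.629), the nucleolar genes Npm1 (-0.624) and Nop56 (-0.589), the elongation factor gene Eef1g (-0.612) and Irf8 (-0.621). Among the 18 primary granule members 15 had a positive rho, with a median of 0.264, and among 11 monocyte-dendritic members 2 did, with a median of -0.237.

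Of 6572 genes, 4 correlated with the monocyte-dendritic score at 0.5 or more, against a permuted mean of 0.10 and a highest permuted count of 1. The count was 2 with the poor quality cell included and 9 with a plain mean of members. The 4 genes were Irf8 (rho 0.654), the galectin gene Lgals1 (0.556), Dhx38 (0.519) and S100a10 (0.517), followed below the limit by Psap (0.493), the chemokine gene Ccl3 (0.464) and Milr1 (0.449). S100a8 lay at -0.5 or less (-0.505), a count of 1 that 10 of 100 permutations also reached and that ran from 0 to 4 under other settings, and Pglyrp1 (-0.483) and S100a9 (-0.431) followed. Among the 18 primary granule members the median rho with this score was only -0.1085, and 0 lay at -0.5 or less. Their values ran from -0.416 (Fcnb) to 0.148 (Mpo), with 3 above 0, so the negative relation of the 2 scores was not uniform over members. The cell cycle score had 30 of 6505 genes at 0.5 or more, against a permuted mean of 0.10, and 0 at -0.5 or less. They included the tubulin genes Tubb5 (0.698) and Tuba1b (0.563), the histone genes Hist1h2ao (0.624) and Hist1h2ae (0.620), Esco2 (0.620), Kif15 (0.620), Cenpu (0.607) and Ncapg (0.572). The lowest values among the genes taken by the naming rule were those of Ftl1 (-0.438), Ostc (-0.433) and Tyrobp (-0.416). A further histone gene, Hist1h2ap, also lay on the negative side (-0.384). Histone genes of 1 family and tubulin genes can share reads, so their single values are uncertain. With the number of detected genes partialled out, 4 genes correlated with the cell cycle score at 0.5 or more, and with a plain mean of members 48 did.

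Irf8 and Gfi1, whose products are known to act against each other in the choice between monocyte and neutrophil fates, were set against all 5 scores, with adjustment over 10 relations. This comparison was added after the Irf8 levels had been seen, but before its relations to the scores had been. In the ranking above, Irf8 stood first among 6572 genes along the monocyte-dendritic score. Irf8 correlated with the primary granule score at rho -0.685 (Pearson r -0.635), with the late neutrophil score at -0.621 (r -0.663) and with the monocyte-dendritic score at 0.654 (r 0.620), each at p = 1e-05 for either coefficient, the smallest the permutations can give, and adjusted p = 3.33e-05. Without the 2 cells farthest from the median, r was -0.650, -0.633 and 0.600. Within the clusters of 33 and 29 cells, rho was -0.566 and -0.733 for the primary granule score, -0.463 and -0.821 for the late neutrophil score, and 0.587 and 0.841 for the monocyte-dendritic score. Irf8 did not pass the threshold with the stem and early progenitor score (rho 0.192, adjusted p = 0.135) or the cell cycle score (rho -0.205, adjusted p = 0.126). It passed with the former with a plain mean (rho 0.292). With the latter it passed without the 7 cells with fewest genes (rho -0.348) or with the number of detected genes partialled out (rho -0.353). Within the clusters, rho was 0.222 and 0.192 for the stem and early progenitor score, and -0.491 and -0.316 for the cell cycle score.

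**Figure D3:**
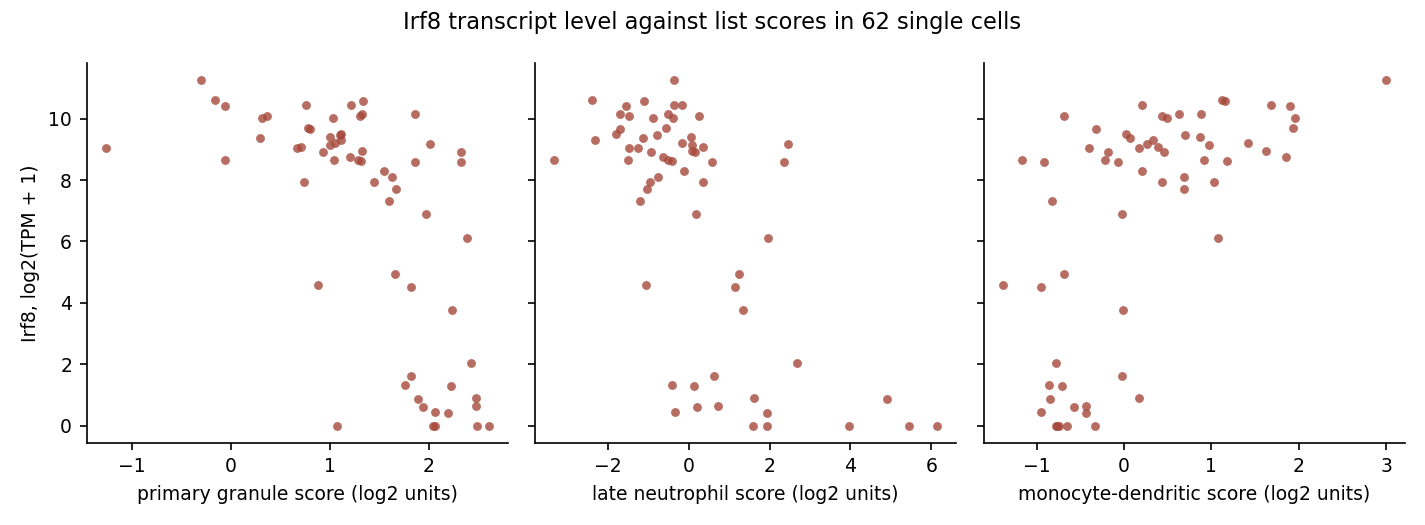
Irf8 transcript level as log2(TPM + 1) against the primary granule, late neutrophil and monocyte-dendritic scores, in log2 units relative to control genes, with 1 point for each of 62 cells. Irf8 is lower in cells with high primary granule and late neutrophil scores (rho -0.685 and -0.621) and higher in cells with a high monocyte-dendritic score (rho 0.654).

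Gfi1 took the opposite sign with the monocyte-dendritic score (rho -0.396, p = 0.00165, adjusted p = 0.00412, Pearson r -0.387, p = 0.00206, r without 2 cells -0.380). Its rho was 0.281 with the primary granule score (p = 0.0279) and 0.285 with the cell cycle score (p = 0.0251), each at adjusted p = 0.0465, and both missed the threshold under other settings. It did not pass with the late neutrophil score (rho 0.203, adjusted p = 0.126), although it did with the number of detected genes partialled out (rho 0.321) and with a plain mean (rho 0.289). With the stem and early progenitor score (rho -0.265, adjusted p = 0.0528) it passed only with the granule members removed (rho -0.293). Pearson's r was 0.264 with the primary granule, 0.229 with the cell cycle, 0.201 with the late neutrophil and -0.304 with the stem and early progenitor score, of which the last alone passed (adjusted p = 0.032). Within the clusters of 33 and 29 cells Gfi1 correlated with the monocyte-dendritic score at -0.381 and -0.310. It correlated with the primary granule score at 0.143 and 0.438 and with the cell cycle score at 0.376 and 0.0248. The late neutrophil score gave 0.137 and 0.393, and the stem and early progenitor score -0.458 and -0.122. Irf8 and Gfi1 transcripts were detected together in 27 cells, against 28.0 expected from their separate shares, while their levels had a rho of -0.341 (Pearson r -0.269, r without 2 cells -0.350). This pair was chosen after the other correlations were seen, so no p is given for it.

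The genes that varied most between cells beyond the trend with mean level were Rps27, Chil3, S100a9, S100a8 and Rps27rt. Chil3, a chitinase-like gene of neutrophils, averaged 3724 ± 9456 TPM and was detected in 57 cells, and S100a9 averaged 4627 ± 13925 TPM. Fcnb (rank 7), Cd63 (rank 8), Mrgpra2b (rank 9) and Irf8 (rank 12) followed. Rps27 and Rps27rt are near-identical copies whose reads can be split between them, so their variation is uncertain.

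Clustering on 500 variable genes, with the marker and cell cycle lists left out, gave 2 clusters of 33 cells (53.2%, exact interval 40.1 to 66.0%) and 29 cells (46.8%, 34.0 to 59.9%). The mean silhouette was 0.141, and 0.136 with 3 clusters. In simulated data it was 0.123 with planted groups of cells and 0.0854 with shuffled values alone. With the poor quality cell included, the division had an adjusted Rand index of 0.223 with this one, where 1 stands for an identical division. The split was therefore not stable, and values within clusters hold for this division only. The clusters differed in the number of detected genes, 4389 ± 345 in cluster 1 and 3530 ± 402 in cluster 2, and the first principal component followed that number (rho -0.922). Cell cycle scores, from list members left out of the clustering, averaged 0.54 ± 0.60 in cluster 1 and -0.66 ± 0.63 in cluster 2. Other genes that rise with this score, such as Hist1h2ao (rho 0.624), were not left out. The difference in cell cycle scores is therefore not independent of the clustering. Late neutrophil scores averaged -0.42 ± 1.57 and 0.80 ± 1.88, and monocyte-dendritic scores -0.03 ± 0.78 and 0.53 ± 1.03, so both overlapped widely between the clusters. By difference of mean log2(TPM + 1) from the other cells, Cd48 (4.92), Tk1 (4.76) and Hist1h2ao (4.35) led cluster 1. Chil3 (2.59) led cluster 2, followed by the monocyte-dendritic member Cd14 (2.40), with S100a9 (2.21) and S100a8 (2.14) also among its leading genes. The spread was wide, since Chil3 averaged 7.28 ± 5.40 in cluster 2 and 4.69 ± 4.16 in the other cells. A naming rule fixed beforehand rested on list markers among the leading genes, and would have called cluster 2 late neutrophil-like. That rule was not applied, since the number of detected genes moves with the clusters, and the clusters were kept by number.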

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

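The cell marked as poor quality, which was left out of the main comparisons and entered only as an alternative setting, gave signals of its own. It had 801 genes at 1 TPM, a median Spearman correlation of 0.289 with the other cells and 14 of 18 primary granule members at 1 TPM or more, with Mpo at 29282 TPM. Irf8 stood at 1575 TPM in that cell. Both results drew attention because they come from data outside the main comparisons.

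Irf8 transcript in cells labelled Irf8-/- was weighed against 5 explanations, of which the test of a fixed total was chosen only after the result was seen. The tables argue against shared reads, as 0% of the 31-base stretches of Irf8 transcripts lie in another gene with a mean of at least 100 TPM, while the test of a fixed total decides nothing: removing the abundant granule and late neutrophil members rescales a cell by at most 1.55-fold, so the rho of Irf8 with the monocyte-dendritic score (0.671 after removal) could hardly have moved. Cells with a working Irf8 gene among the 62, a mixed sample and so a technical explanation, may be a source, since the predicted relation with the monocyte-dendritic score was present (rho 0.654, 95% bootstrap interval 0.493 to 0.759), but a transcript without function under normal upstream control would give the same relation. The number of detected genes stays open as an influence (rho 0.159, -0.121 to 0.419, just past the limit of 0.4 set for excluding it). Transcription of a part of Irf8 outside a deletion cannot be told apart from a whole transcript, because the 82.3% of cells with Irf8 is a share at the gene level, and no biological explanation was tested.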

How the results depend on the processing

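The alternatives for Irf8 and Gfi1 against the scores, and the omission of Ly6a and Cxcr2, were chosen after seeing the data, and the others before the data were examined. All 600 checks of the genes named along a score kept their sign. These genes were picked as the extremes in the same cells, so the kept signs decide nothing. The size of rho did move over the settings. Along the cell cycle score it ran from -0.487 to -0.185 for Lrrc58 and from 0.520 to 0.818 for Tubb5. The primary granule with late neutrophil correlation, and those of Irf8 with the primary granule, late neutrophil and monocyte-dendritic scores, kept direction and call under each alternative run. For Irf8 and Gfi1, however, the settings without the low-value filter, with z-scored members and with 1 member left out were not run. Some score pairs missed the threshold under those settings, so the Irf8 relations were checked less widely than the score pairs. No paired analysis was possible because the series holds 1 group. Unknown read depth limits all detection shares. Where no cause is named, the cause was not tested.

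With any value above 0 as detected, which lowers the limit by construction, shares of cells were 91.9% for Irf8 and, for 3 list members, 12.9% (basophil and mast cell), 17.7% (macrophage) and 100% (G2/M, stress, apoptosis regulator). At 10 TPM they were 61.3% (stem), 0% (stromal) and 83.9% (G2/M). The apoptosis share was 100% without the 7 cells with fewest genes and with size factors. Coordination without the low-value filter was 0.0425 (stem) and -0.0202 (macrophage). The macrophage value was -0.115 without the 7 cells and -0.138 with detected genes partialled out, where the transcription factor value was -0.00891.

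The primary granule with monocyte-dendritic rho was -0.184 with z-scored members. The late neutrophil with monocyte-dendritic rho was -0.248 (pseudocount 0.1), -0.263 (no filter), -0.272 (poor quality cell included), -0.279 (without the 7 cells) and -0.232 (without Ccr2). The late neutrophil with stem rho was -0.310 without Ly6a and Cxcr2 and -0.321 without Ly6a, now past the threshold. The monocyte-dendritic with cell cycle rho was -0.293 (pseudocount 10, and without Cd14), and no relation was seen at -0.00531 (z-scored) or 0.00562 (plain mean).

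Genes along the late neutrophil score numbered 29 and 13 with size factors. Along the monocyte-dendritic score, those at 0.5 or more numbered 2 (poor quality cell included) and 9 (plain mean), and those at -0.5 or less 0 (pseudocount 0.1), 3 (without the 7 cells), 4 (partialled) and 3 (plain mean). Along the cell cycle score, 4 (partialled) and 48 (plain mean) lay at 0.5 or more, and 1 (without the 7 cells) and 1 (plain mean) at -0.5 or less. Irf8 passed with the stem score at 0.292 (plain mean) and with the cell cycle score at -0.348 (without the 7 cells) and -0.353 (partialled). Gfi1 lost the primary granule call at 0.271 (pseudocount 0.1), 0.213 (poor quality cell), 0.247 (without the 7 cells) and 0.248 (plain mean), and the cell cycle call at 0.278 (pseudocount 0.1), 0.272 (poor quality cell) and 0.215 (partialled). It passed with the late neutrophil score at 0.321 (partialled) and 0.289 (plain mean), and with the stem score at -0.293 (granule members removed). The largest cluster held 30.6% of cells with 4 clusters, 29.0% with 5 and 71.4% with the poor quality cell included. The adjusted Rand index with the main division was 0.506, 0.455 and 0.223.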

Other observations

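The stress and immediate early list, taken as a whole, varied together across the cells, as the granule and cell cycle lists did. The 19 members of the stress and immediate early list detected in at least 10% of cells had a mean pairwise rho of 0.145, above all 10000 matched random lists (percentile 100). Jun, Zfp36, Fos, Nfkbia and Dusp1 led, with Nfkbia and Jund at rho 0.547 and Zfp36 and Dusp1 at 0.499. Not every member took part, since the mean rho with the other members was -0.0113 for Gadd45b and -0.0118 for Hsp90aa1. Fos was detected in 46 cells at 327 ± 442 TPM, and Atf3 in none. At least 3 members of this list were detected in 61 of 62 cells, as were 3 apoptosis regulator members, which did not vary together (percentile 16.0). Of the cytokine receptor genes, Csf3r was detected in 60 cells, Csf2rb in 53 and Csf2ra in 45, while Epor was not detected. Neither the cytokine receptor list (percentile 68.3) nor the interferon response list (percentile 67.4) stood apart, and 3 members of each were found in all 62 cells. The interferon response members detected most often were Ifitm2 (62 cells), Psmb8 (57) and Psmb9 (51). By contrast, 4 of its 32 members (Ifit3, Mx1, Mx2 and Ifi44) reached 1 TPM in no cell, and Isg15 did in 3.

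A set of 10 single genes, chosen after the correlations of Irf8 with the scores were seen, were set against Irf8. The values are given as a description and not as a test. Irf8 was lower where S100a8 (rho -0.748), Fcnb (-0.712), Ets1 (-0.527) and Cebpe (-0.466) were higher, and higher with Csf1r (0.437). The other values were -0.341 for Gfi1, 0.335 for Ctss, 0.322 for Zeb2, 0.201 for Klf4 and -0.187 for Elane.

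In the next pattern both tests were set before their results were seen, although Ly6a and Ly6c2 were by then known to rise with the same score. Some genes were listed above 0 at a low level in nearly every cell: 126 genes with a mean under 60 TPM in at least 95% of cells, among them Tyr, Cxcr2 and Olfr613. Reads shared with abundant genes may account for part of them, since of 121 with a sequence 87.6% had a 31-base stretch in a gene with a mean of at least 100 TPM, against 45.5 to 62.0% in length-matched sets. Ly6a, tested beside these 126 genes, lies outside them at a mean of 65.8 TPM. It shares 84 of 1259 stretches with Ly6c2 and correlated with that gene at rho 0.706 (95% bootstrap interval 0.549 to 0.826). Ly6c2 is therefore a candidate source of the Ly6a values in Sca-1-negative cells. True co-expression of the family members stays open, and no biological explanation was tested.

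The division of cells into 2 clusters followed the number of detected genes, and all of its values below were chosen after the result was seen. More detectable RNA in cycling cells may contribute, since the number of genes and the cell cycle score correlated at rho 0.548 (95% bootstrap interval 0.328 to 0.709). With the cell cycle score partialled out the first principal component kept a correlation of -0.892 with the number of genes, and with the number of genes partialled out it had -0.0333 with the cell cycle score. These 2 values decide nothing here, since cycling could act on the component through the number of genes. Capture or read depth per cell cannot be told apart from RNA content, because the correlation of -0.922 comes from values that keep no read totals.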
